A study of Mus musculus with 8 samples.

How the data were processed

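RNA-seq was performed on primary hepatocytes of male mice that carried AAV8 with GFP (AAV-GFP, 4 libraries) or with mouse Trib3 (AAV-Trib3, 4 libraries), injected at 6 weeks of age and sampled 4 weeks later. Per the labels' protocols, total RNA was treated with DNase, mRNA was enriched on oligo(dT) beads and fragmented, and double-stranded cDNA was ligated to adaptors and amplified by PCR. That protocol names no molecular identifiers and no step that keeps strand. Groups and replicate numbers 1 to 4 come from the sample titles, and each column was matched to its sample by the code given in the title. No sequencing batch or date was given in the sources used here.

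The deposited table holds 34745 mouse genes with Ensembl identifiers, symbols and coordinates. Per the file headers, it has a column of gene counts and a column of FPKM (counts scaled by gene length and by the library's total) for each library, 8 columns of each. The deposited counts are whole numbers without normalisation and were used for all tests. The deposited FPKM were checked against the counts in the 5860 genes with more than 100 counts in every library. The ratio of count to FPKM followed the library totals in all 8 libraries, so the FPKM are the same counts scaled by library size and gene length and were not tested separately. The submitters' processing notes name Trimmomatic, a read trimmer, and the mm10 genome build, without a version of the trimmer. The aligner, the counting program, the annotation release and the treatment of reads that match several genes are not given in the sources used here. Of the gene identifiers, 34267 (98.6%) were found in GENCODE M21, an annotation of the same build, and 27686 (80.8% of those) had the same start and end. In the table, 67 gene names occur more than once, so genes were tracked by identifier.

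Genes were filtered with edgeR's filterByExpr on the group at default settings, which kept 11036 genes. Library sizes were scaled by TMM factors, which ranged from 0.699 in AAV-GFP replicate 2 to 1.15 in AAV-GFP replicate 4. The main test was edgeR's quasi-likelihood F test (glmQLFit with robust estimation, glmQLFTest) of AAV-Trib3 against AAV-GFP with no covariate, Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes were derived from the fold change and the F statistic. Levels are TMM-normalised CPM with the SD over 4 libraries. Gene lists were tested two-sided with camera in limma on log2 CPM (prior count 2), with the preset correlation of 0.01, for lists with at least 5 tested members. Adjusted p-values of lists are over the 32 lists tested. Each list was also tested with an estimated correlation, with fry, and by an exact two-sided permutation of its mean over the 70 relabellings of the libraries. Fry asks whether the genes of a list move one way on balance and does not compare them with other genes. Single values were compared with exact two-sided permutation tests, for which 4 against 4 libraries allow no p below 0.0286. Smaller lists were summed in CPM. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9.

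The test design, the 38 gene lists, the rule for named genes and all alternatives other than those named below as later additions were fixed before the data were examined. The rule named Trib3 always, then up to 12 genes per direction among those past the threshold with an average log2 CPM of at least 1 and groups that do not overlap. As none passed, it named the 10 genes with the smallest unadjusted p. It added up to 4 members with the smallest p of each list whose members are described; a few of these are not reported here. After values had been seen, this description of members was limited to the 9 lists called and 7 lists of stress, lipid, glucose and insulin genes. Rab7, Jund, Zfp36, Sox9, Spp1, Alas2, Saa1, Lcn2, the heat shock genes and the genes called in single left-out fits are named outside the rule, after their values were seen.

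Alternatives were DESeq2 size factors within edgeR, library size alone, Trib3 left out of the scaling, DESeq2's Wald test, limma-voom, no low-count filter and a stricter one (1 CPM in all libraries of a group and an average log2 CPM of 1). Further ones were robust estimation off, the replicate number as a block, a covariate of non-parenchymal marker expression, stricter thresholds, and each of the 8 libraries left out in turn. The exact permutation of list means, the removal of mitochondrial genes before normalisation and the estimated correlation in each refit were added after the data had been seen. The 35 splits of the 8 libraries into 4 and 4 were refitted. Replicates were compared before averaging. The chi-square per degree of freedom between libraries of a group lay between 15.6 and 189, far beyond sampling noise, so all 8 were kept as separate libraries.

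Total counts per library were 11350442, 14247364, 12991039 and 14241096 for AAV-GFP and 15361128, 13712382, 13491058 and 13908488 for AAV-Trib3, in order of replicate number. At these depths a gene with 3 counts has 0.195 to 0.264 CPM, and intervals of counts cover counting error only, since PCR copies were not separated. The common biological coefficient of variation was 27.5%. The pipeline was tested on simulated data made from the real means and library sizes for this comparison, with 11034 genes. Of 50 genes changed at each size, it recovered 44% at 2-fold, 92% at 4-fold, 86% at 8-fold and 86% at 16-fold, with 161 calls in all, 7 of them on unchanged genes. In that run many genes changed at once, which eases the adjusted threshold, and genes varied independently of each other. These rates are therefore not the power of the real comparison, in which Trib3, 18.1-fold higher, had an edgeR adjusted p of 0.0675. The list test was run on simulated data with 11051 genes and 20 lists of 15 genes, and called the 1 list that had been shifted by 0.6 on the log2 scale and 0 others. Those simulated genes vary independently, so this run does not test lists whose members vary together.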

Results

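Poly(A)-selected RNA was sequenced from primary hepatocytes of male mice that had received an adeno-associated virus of serotype AAV8. The virus carried mouse Trib3 (AAV-Trib3, 4 libraries) or, as the control, GFP (AAV-GFP, 4 libraries). Mice were 6 weeks old at injection, and hepatocytes were isolated 4 weeks later. Each library had a column of gene counts for 34745 Ensembl genes, of which 17137 had 0 counts in all 8 libraries and 11036 were expressed highly enough to be tested. Total counts ran from 11350442 in AAV-GFP replicate 1 to 15361128 in AAV-Trib3 replicate 1, and their means did not differ beyond the spread between libraries (exact two-sided permutation test, p = 0.371). The labels number the libraries of each group but do not say that each came from a separate mouse. P-values of single genes and of permutation tests thus measure the spread between these libraries, part of which may be technical. Those of camera with its preset correlation compare the genes of a list with other genes, and largely leave out variation that members share between libraries.

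The comparison asked what raised Trib3 expression does to the transcripts of hepatocytes. Trib3 encodes a pseudokinase that is induced by ATF4 and is known to bind AKT. Trib3 transcripts were 18.1-fold higher in AAV-Trib3 than in AAV-GFP hepatocytes, at 44.5 ± 23.9 against 2.40 ± 0.94 CPM (counts scaled to a common library size with TMM factors; SD, n = 4 each). All 4 AAV-Trib3 libraries lay above all 4 AAV-GFP libraries, which gave an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 libraries allow. Within AAV-Trib3 the level was uneven, with 62.6 and 67.2 CPM in replicates 2 and 3 and 27.9 and 20.2 CPM in replicates 1 and 4. The gene (ENSMUSG00000032715) is a protein-coding gene on the minus strand of chromosome 2, from 152337422 to 152344032 in mm10. Its counts rested on 458, 854, 881 and 299 reads in AAV-Trib3 replicates 1 to 4 and on 32, 11, 34 and 55 in AAV-GFP. Before normalisation, the highest AAV-GFP library (replicate 4) had 3.86 CPM, with an exact Clopper-Pearson 95% interval of 2.91 to 5.03. The lowest AAV-Trib3 library (replicate 4) had 21.5 CPM, with an interval of 19.1 to 24.1, and these intervals cover counting error only. Counts at the gene do not separate vector transcripts from endogenous ones.

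**Figure D1:**
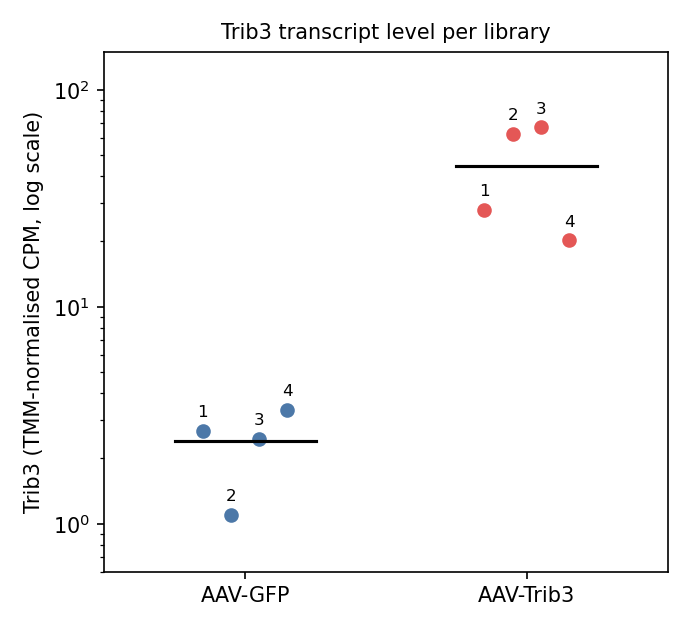
Trib3 transcript level in each library, in TMM-normalised CPM on a log axis. Points are libraries labelled with their replicate number and bars are group means; the AAV-Trib3 libraries lie between 20.2 and 67.2 CPM and the AAV-GFP libraries between 1.1 and 3.36 CPM.

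In the edgeR quasi-likelihood test across all genes, Trib3 had a log2 fold change of 4.17 ± 0.47 (SE), an unadjusted p of 6.12e-06 and a Benjamini-Hochberg adjusted p of 0.0675, just outside the threshold of 0.05. No gene was called by edgeR, 0 higher and 0 lower. At an unadjusted p under 0.05, edgeR listed 346 genes (150 higher and 196 lower with AAV-Trib3), where chance alone gives 552. The groups did not overlap in 253 genes, 2.29% of those tested, against 2.86% by chance. DESeq2 called 6 genes and limma-voom 0. The DESeq2 calls were Trib3 (adjusted p = 1.03e-17), Rab7 and Tiam2, which rose in that test, and Cyp2c40, Actg1 and Tenm3, which fell in it. The precision was moderate: the median SE of a log2 fold change was 0.216, and the SE was under 0.5 for 92.1% of genes. Without AAV-Trib3 replicate 4, Trib3 passed edgeR's threshold (log2 fold change 4.42, adjusted p = 0.0206).

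The 10 genes with the smallest unadjusted p in edgeR were Trib3, Actg1, Tenm3, Tiam2, Dock1, Adora1, Cyp2c40, Cd82, Cars and Golm1. All but Trib3 had an edgeR adjusted p of 1, so by that test their values are descriptions of these libraries. Among them DESeq2 called Cyp2c40 (adjusted p = 0.00229), Actg1 (0.00314), Tenm3 (0.00368) and Tiam2 (0.00755), calls that edgeR and limma-voom did not share. Actg1, the gene of cytoplasmic gamma-actin, stood at 18.7 ± 3.8 CPM with AAV-Trib3 and 43.71 ± 11.01 CPM with AAV-GFP (SD, n = 4). Tenm3, a transmembrane teneurin, stood at 9.96 ± 2.41 against 22.8 ± 4.8 CPM. Levels were higher with AAV-Trib3 for Tiam2 and Dock1, both exchange factors that activate the GTPase Rac. Tiam2 had 10.4 ± 4.0 against 3.62 ± 0.81 CPM, a log2 difference of 1.53 ± 0.30 (SE), and Dock1 had 19.3 ± 1.8 against 12.7 ± 1.3 CPM, a log2 difference of 0.60 ± 0.13. Golm1, a Golgi membrane protein, had 3.73 ± 1.04 against 1.14 ± 0.51 CPM. Levels were lower for the adenosine receptor Adora1 (log2 difference −0.83 ± 0.19), the tetraspanin Cd82 (−0.61 ± 0.14) and the cysteinyl-tRNA synthetase Cars (−0.79 ± 0.18). The cytochrome P450 gene Cyp2c40 had 3.86 ± 1.66 CPM with AAV-Trib3, while the AAV-GFP libraries scattered around 29.2 ± 26.9 CPM, and its log2 difference of −2.91 ± 0.65 was −2.10 without AAV-GFP replicate 2. Cyp2c40 has close paralogs and Actg1 has processed pseudogenes, so their counts are uncertain where reads could be split between copies.

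Of 38 gene lists chosen before the data were examined, 32 had at least 5 tested members, and 9 passed an adjusted p of 0.05 in camera with its preset correlation of 0.01. No list was called with an estimated correlation, by fry or by an exact permutation of the list means, and no list member passed edgeR's threshold over all genes. The permutation could hardly have called a list. Its smallest possible p, 0.0286, passes after adjustment over 32 lists only if most of them reach it. Genes of the periportal zone of the liver lobule were higher with AAV-Trib3, and genes of the pericentral zone and of xenobiotic metabolism were lower. All 10 periportal genes were higher, and the mean log2 CPM of the list was 7.65 ± 0.46 with AAV-Trib3 and 7.19 ± 0.06 with AAV-GFP (SD, n = 4). Each AAV-Trib3 library lay above each AAV-GFP library in that mean, with the highest value, 8.31, in AAV-Trib3 replicate 3. Camera gave an adjusted p of 1.05e-04, or adjusted p = 0.6 with an estimated correlation, and the exact permutation p of the list mean was 0.0286 (0.855 adjusted over the lists). Adjusted over the list alone, 1 member passed in edgeR: Gls2, the liver-type glutaminase, at 220.6 ± 55.7 against 129 ± 5.3 CPM. Other members with small p were Ctsc (log2 difference 0.85 ± 0.30), the cytochrome P450 Cyp2f2 (0.59 ± 0.29) and the serine dehydratase Sds (0.77 ± 0.41, and 0.18 without AAV-Trib3 replicate 3).

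Xenobiotic metabolism genes were lower for 15 of 17 tested members, with a median log2 difference of −0.45 (camera adjusted p = 1.05e-04; adjusted p = 0.6 with an estimated correlation). Adjusted over the list alone, 0 members passed in edgeR, and 2 had an unadjusted p under 0.05. These were Ugt1a1, which conjugates bilirubin, at 472 ± 27 against 708 ± 121 CPM, and the cytochrome P450 Cyp1a2, at 569 ± 30.0 against 830.0 ± 191 CPM (SD, n = 4). The P450 genes Cyp2c29 and Cyp2a5 had log2 differences of −0.47 ± 0.24 and −0.54 ± 0.30 (SE), and both belong to clusters of similar genes. Pericentral genes were lower for 9 of 10 members (camera adjusted p = 0.00374; adjusted p = 0.6 with an estimated correlation; 0 past edgeR's threshold adjusted over the list alone). Cyp1a2 and Cyp2e1 are on both of these lists. The pericentral genes Lect2, Cyp2e1 and Oat had log2 differences of −0.45 ± 0.26, −0.40 ± 0.23 and −0.42 ± 0.27. The mean log2 CPM of the pericentral list was 5.96 and 6.19 in AAV-Trib3 replicates 2 and 3. In AAV-Trib3 replicates 1 and 4 it was 6.76 and 6.91, within the 6.54 to 7.2 of AAV-GFP. The pericentral call was lost without AAV-GFP replicate 2 (adjusted p = 0.0923), AAV-Trib3 replicate 2 (0.0941) or AAV-Trib3 replicate 3 (0.0655).

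Urea cycle and amino acid catabolism genes were higher for 12 of 18 members, with a median log2 difference of 0.16 (camera adjusted p = 0.0172; adjusted p = 0.6 with an estimated correlation). Gls2 again was the 1 member past edgeR's threshold adjusted over the list alone. Next came Sdsl (log2 difference 0.55 ± 0.28), the histidine ammonia-lyase Hal (0.61 ± 0.32) and the argininosuccinate lyase Asl (0.38 ± 0.22). Gls2, Hal and Arg1 are also on the periportal list, and Oat, which was lower, is also on the pericentral list. This call was lost without AAV-GFP replicate 2 (adjusted p = 0.0538), AAV-GFP replicate 4 (0.147) or AAV-Trib3 replicate 3 (0.163).

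**Figure D2:**
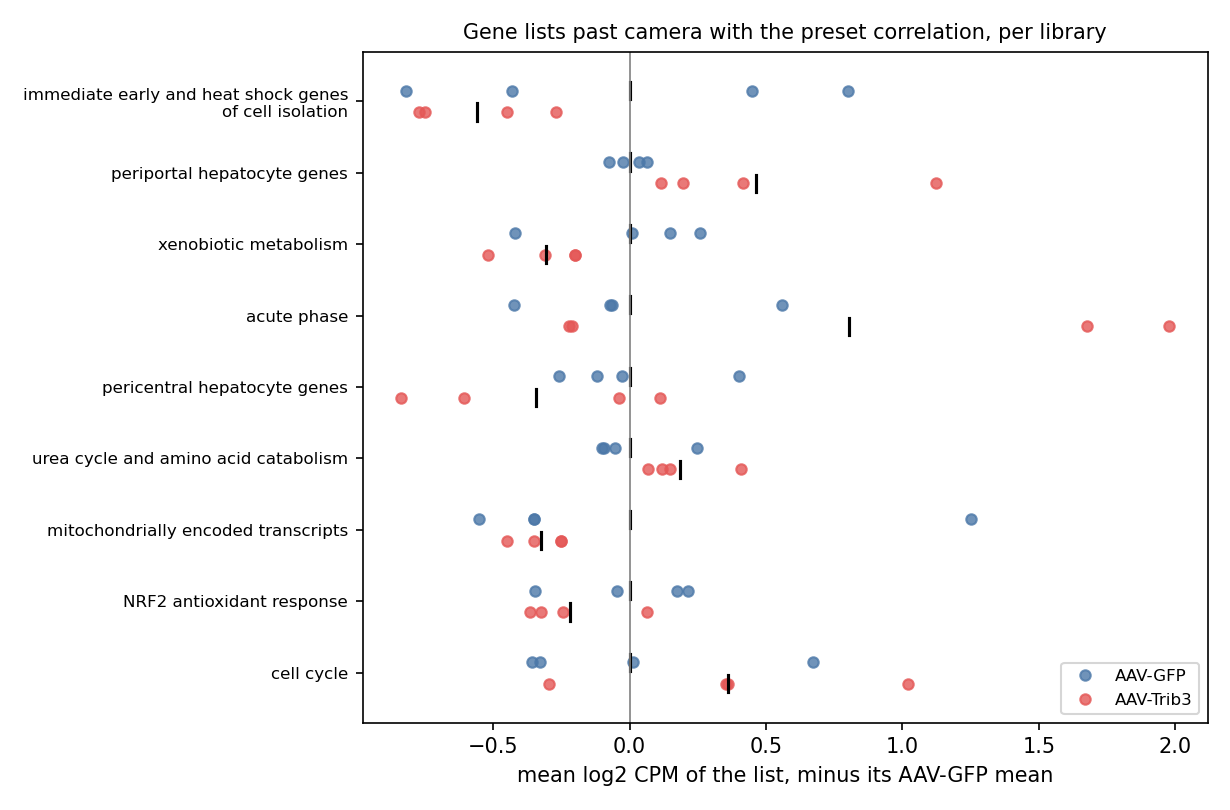
Mean log2 CPM of the 9 gene lists past camera's threshold with the preset correlation, in each library, after subtraction of the list's AAV-GFP mean. Points are libraries (blue AAV-GFP, red AAV-Trib3) and black bars are group means; the AAV-Trib3 and AAV-GFP libraries are fully separated for the periportal list, and a single AAV-GFP library (replicate 2) stands far to the right for mitochondrially encoded transcripts.

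Immediate early and heat shock genes, which respond rapidly to stress such as cell isolation, were lower with AAV-Trib3 for 11 of 14 tested members (median log2 difference −0.72). Camera gave an adjusted p of 1.05e-04, or adjusted p = 0.6 with an estimated correlation, and the exact permutation p of the list mean was 0.314. Adjusted over the list alone, 6 members passed in edgeR, all of them lower: Ier2, Junb, Egr1, Jun, Jund and Zfp36. The transcription factor Egr1 stood at 52.2 ± 12.6 against 212 ± 173 CPM, and Junb at 35.4 ± 7.3 against 81.7 ± 36.0 CPM (SD, n = 4). Jun stood at 106 ± 28 against 217 ± 90 CPM, and Ier2 at 24.3 ± 2.6 against 59.4 ± 28.4 CPM. The 11 immediate early genes had a median log2 difference of −1.03, and the exact permutation p of their mean was 0.143. The 3 heat shock genes went both ways, with log2 differences of −0.34 ± 0.83 for Hspa1a, 1.02 ± 0.85 for Hspa1b and 0.40 ± 0.38 for Dnajb1 (SE). Their mean log2 CPM was 5.14 in AAV-Trib3 replicate 2 and between 2.62 and 2.9 in the other AAV-Trib3 libraries, which lay below the AAV-GFP mean of 3.22. AAV-GFP libraries were spread widely in the immediate early genes, from a mean log2 CPM of 4.7 in replicate 2 to 6.4 in replicate 4, while AAV-Trib3 libraries lay between 4.73 and 5.13.

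Acute phase genes, which the liver induces in inflammation, were higher with AAV-Trib3 for 18 of 20 members (median log2 difference 0.66; camera adjusted p = 2.94e-04; adjusted p = 0.6 with an estimated correlation). In edgeR, 0 members passed adjusted over the list alone, and 4 had an unadjusted p under 0.05: Saa3, Saa2, Orm2 and Hpx. The highest levels were in AAV-Trib3 replicates 1 and 4. The mean log2 CPM of the list was 8.89 and 8.59 there, 6.69 and 6.70 in AAV-Trib3 replicates 2 and 3, and 6.49 to 7.47 in AAV-GFP, and the exact permutation p between the groups was 0.314. The serum amyloid gene Saa2 had 35388 and 35753 counts in AAV-Trib3 replicates 1 and 4, against 227 and 244 in replicates 2 and 3 and at most 2062 in AAV-GFP. Orm2, an acid glycoprotein, had 286 ± 331 against 26.0 ± 25.5 CPM, and the haem-binding protein Hpx had 6508 ± 2969 against 3294 ± 1337 CPM (SD, n = 4). Saa3 had 22.2 ± 30.7 against 3.90 ± 1.21 CPM, and its log2 difference of 2.50 ± 0.86 was 0.83 without AAV-Trib3 replicate 1. Those of Saa2 and Orm2 ran from 3.69 to 5.48 and from 2.56 to 4.41 when 1 library was left out, highest without AAV-GFP replicate 3 and AAV-GFP replicate 2. The serum amyloid and acid glycoprotein genes have near-identical copies, so counts of single members are uncertain. In the same libraries, macrophage and Kupffer cell markers had a mean log2 CPM of 2.97 and 2.41, against −0.0482 and 1.07 in AAV-Trib3 replicates 2 and 3, so within AAV-Trib3 they were highest where the acute phase genes were. Within AAV-GFP these markers were 2.66 and 2.51 in replicates 2 and 4 and 0.0857 and −0.175 in replicates 1 and 3, where the acute phase mean was 6.84 and 6.49 and 6.85 and 7.47. Trib3 was lower in AAV-Trib3 replicates 1 and 4 than in AAV-Trib3 replicates 2 and 3.

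**Figure D3:**
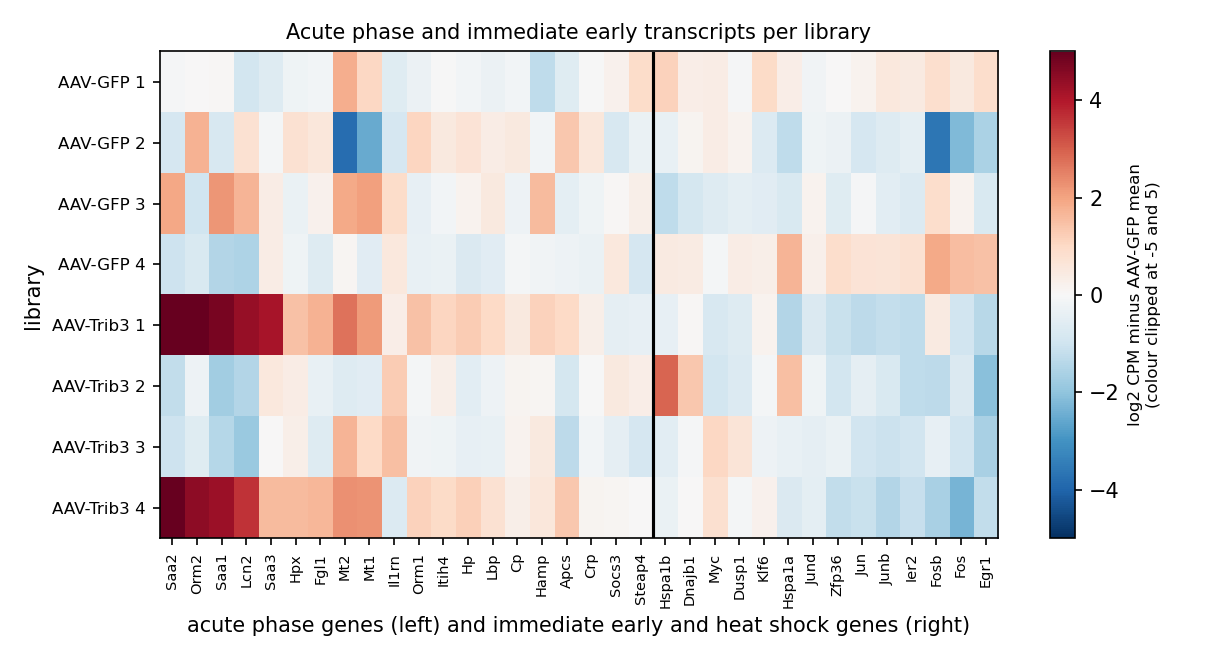
Log2 CPM of the 20 acute phase genes (left of the line) and the 14 immediate early and heat shock genes (right of it) in each library, minus the AAV-GFP mean of the gene; red is higher, blue is lower and the colour scale is clipped at its ends. Saa2, Orm2, Saa1 and Lcn2 are highest in AAV-Trib3 replicates 1 and 4, and Jun, Junb, Ier2 and Egr1 are below their AAV-GFP means in all 4 AAV-Trib3 libraries.

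Mitochondrially encoded transcripts were lower with AAV-Trib3 for 13 of 13 members (camera adjusted p = 0.0199; adjusted p = 0.812 with an estimated correlation). This rested on AAV-GFP replicate 2, where these transcripts took 32% of all counts against 14.9% to 18.5% in the other libraries; without it the list was higher with AAV-Trib3 (adjusted p = 0.0367), and without AAV-Trib3 replicate 4 the call was lost (0.0831). Only mt-Nd6 passed in edgeR adjusted over the list alone, at 49.5 ± 15.7 against 164 ± 120 CPM (SD, n = 4), a log2 difference of −1.72 ± 0.44 (SE) that was −1.08 without AAV-GFP replicate 2. It is encoded on the opposite strand from the other members, and no strand setting of the counting was given, so reads of its antisense neighbours cannot be excluded. The respiratory complex I genes mt-Nd5, mt-Nd1 and mt-Nd4l had log2 differences of −0.61 ± 0.43, −0.49 ± 0.37 and −0.45 ± 0.37 (SE).

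Antioxidant genes of the NRF2 response were lower for 13 of 16 members (camera adjusted p = 0.0199; adjusted p = 0.709 with an estimated correlation; 0 past edgeR's threshold adjusted over the list alone). Osgin1 and the haem oxygenase Hmox1 had log2 differences of −0.62 ± 0.28 and −0.56 ± 0.26, and Srxn1 and Gstm3 had −0.35 ± 0.21 and −0.35 ± 0.24. The NRF2 call was lost without AAV-GFP replicate 1 (adjusted p = 0.115) or 4 (0.182) and without AAV-Trib3 replicate 1 (0.0508), 2 (0.0956) or 4 (0.0831). Cell cycle genes were higher for 9 of 11 tested members (camera adjusted p = 0.045; adjusted p = 0.762 with an estimated correlation; 0 past edgeR's threshold adjusted over the list alone), at low levels. Rrm2 had 7.74 ± 1.73 against 5.23 ± 2.12 CPM, and the group means of Cdk1, Mcm2 and the proliferation marker Mki67 were at most 2.17 CPM, with 5.47 CPM of Mki67 in AAV-Trib3 replicate 4. The log2 difference of Mki67 was 1.33 ± 0.97 and ran from 0.33 to 3.21 when 1 library was left out, the highest without AAV-GFP replicate 4. The cell cycle call was lost without AAV-GFP replicate 2 (adjusted p = 0.161) or 3 (0.237) and without AAV-Trib3 replicate 1 (0.0518) or 4 (0.393). It was also lost with limma-voom (0.0734), a stricter low-count filter (0.0983), the non-parenchymal covariate (0.121) and without mitochondrial genes (0.0677).

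The lists closest to the known partners of Trib3 did not pass in the main test. Targets of ATF4 in the integrated stress response were lower for 11 of 15 tested members (camera adjusted p = 0.0587). Their mean log2 CPM was 2.98 ± 0.15 against 3.27 ± 0.22 (SD, n = 4; exact permutation p = 0.0857). Of these, Ppp1r15a, a phosphatase subunit of the stress response, had a log2 difference of −0.48 ± 0.22, Atf3 −1.47 ± 0.78 (−0.75 without AAV-GFP replicate 4 and −2.25 without AAV-Trib3 replicate 2) and the asparagine synthetase Asns −1.20 ± 0.65. Ddit4 had 1.28 ± 0.76, which turned to −0.12 without AAV-Trib3 replicate 3. The list of ATF4 targets passed in 5 of the 8 fits that left out 1 library each (camera adjusted p from 0.00194 to 0.0873 over the 8), those without AAV-GFP replicate 1 or 3 or AAV-Trib3 replicate 2, 3 or 4. With all libraries it passed with limma-voom (0.0476), with no low-count filter (0.00102) and with library size alone (0.0146). With an estimated correlation it did not, at an adjusted p of 0.6 in the main fit and between 0.368 and 0.798 in the fits in which it passed. In the main fit the estimated correlation was −0.033, and camera's unadjusted p was 0.0454 with it and 0.0183 with the preset value. Variation shared by the members is thus not what raised the p in that fit. Insulin and AKT signalling genes were split, 8 higher and 9 lower (camera adjusted p = 0.757), and the log2 differences of Mtor, Irs1, Tsc1 and Gsk3b lay between −0.27 and 0.42.

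Among metabolic lists, cholesterol synthesis and uptake genes were lower for 21 of 21 members (camera adjusted p = 0.0589), with a log2 difference of −0.74 ± 0.51 for Idi1. Mvk and Fdft1 had −1.10 ± 0.66 and −0.91 ± 0.61. Without AAV-GFP replicate 2, in which this list's mean was 7.44 against 4.98 to 6.54 in the other AAV-GFP libraries, the list was higher with AAV-Trib3 (adjusted p = 0.187). Fatty acid and triglyceride synthesis genes were lower for 17 of 20 members (camera adjusted p = 0.0589), among them the transcription factor Mlxipl (−0.66 ± 0.29), Agpat2 (−0.71 ± 0.39), Me1 (−0.49 ± 0.27) and Acss2 (−0.39 ± 0.31). Genes of fatty acid oxidation and PPARA targets went both ways, 11 higher and 13 lower (camera adjusted p = 0.102). In edgeR, 2 of them passed adjusted over the list alone, both lower: Vnn1 at 28.9 ± 2.9 against 59.3 ± 22.0 CPM, and the fatty acid transporter Cd36 at 14.4 ± 5.0 against 39.7 ± 18.2 CPM (SD, n = 4). The fatty acid hydroxylases Cyp4a14 and Cyp4a10 had log2 differences of −2.40 ± 0.73 and −1.42 ± 0.71, carried mostly by AAV-GFP replicates 2 and 3. Cyp4a14 had 1620 and 2020 CPM there, 339 and 226 in AAV-GFP replicates 1 and 4, and 69.1 to 292 in AAV-Trib3. Cyp4a10 had 2250 and 2190 CPM there, 374 and 263 in AAV-GFP replicates 1 and 4, and 199 to 754 in AAV-Trib3. Glycolysis genes were higher for 10 of 15 members (camera adjusted p = 0.0589), with 0.29 ± 0.14 for Eno1, 0.22 ± 0.12 for Pfkl and 0.28 ± 0.20 for Gapdh. Gluconeogenesis genes were higher for 8 of 11 members (camera adjusted p = 0.214), with 0.34 ± 0.16 for Fbp1, 0.41 ± 0.38 for Tat and −0.64 ± 0.58 for Igfbp1. Without AAV-Trib3 replicate 3 the gluconeogenesis direction turned (adjusted p = 0.821).

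Some of these metabolic lists passed camera's threshold under other settings or when a single library was left out. Fatty acid and triglyceride synthesis passed without AAV-GFP replicate 3 (adjusted p = 0.00457) and without AAV-Trib3 replicate 2 (0.0104) or 3 (0.00266). With all libraries it passed with limma-voom (0.0486), no low-count filter (0.0172) and library size alone (0.0146). Cholesterol synthesis passed as lower without AAV-GFP replicate 1 (0.0205) or 3 (1.46e-08) and without AAV-Trib3 replicate 3 (0.0117). With all libraries it passed with the non-parenchymal covariate (8.24e-04), limma-voom (0.0486) and library size alone (0.0028). PPARA targets passed as lower without AAV-GFP replicate 2 (0.00467) or 4 (0.00918) and without AAV-Trib3 replicate 2 (0.00776), and turned to higher without AAV-GFP replicate 3 (0.559). They also passed with library size alone (0.0183). Glycolysis passed without AAV-GFP replicate 1 (0.049) or AAV-Trib3 replicate 1 (0.0183) and with limma-voom (0.0486), and gluconeogenesis without AAV-Trib3 replicate 1 (0.0278). With an estimated correlation, adjusted p for these 5 lists lay between 0.6 and 0.812 in the main fit and between 0.471 and 0.87 in the fits in which they passed.

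Markers of other liver cell types were present at low levels, apart from Alas2 on the erythroid and platelet list. Macrophage and Kupffer cell markers were higher for 10 of 12 tested members, with a mean log2 CPM of 1.60 ± 1.36 with AAV-Trib3 and 1.27 ± 1.52 with AAV-GFP (SD, n = 4; exact permutation p = 0.686; camera adjusted p = 0.377). This list passed as higher without AAV-GFP replicate 4 (adjusted p = 0.0406) or AAV-Trib3 replicate 2 (0.00751), and turned to lower without AAV-GFP replicate 1 (0.823) or 3 (0.558) or AAV-Trib3 replicate 1 (0.646). It did not pass with an estimated correlation, either with all libraries (adjusted p = 0.859) or without AAV-GFP replicate 4 (0.704) or AAV-Trib3 replicate 2 (0.772). Sinusoidal endothelial markers were split, 6 higher and 6 lower (camera adjusted p = 0.134), with a median log2 difference of 0.02 and a mean of −0.02 while camera's direction was higher; the list passed without AAV-GFP replicate 4 (5.47e-05) and turned to lower without AAV-GFP replicate 3 (0.152). Its adjusted p with an estimated correlation was 0.812 with all libraries and 0.588 without AAV-GFP replicate 4. Stellate cell and fibroblast markers were lower for 4 of 6 tested members, with a median log2 difference of −0.38, again against camera's direction (adjusted p = 0.5). Cholangiocyte markers summed to 18.1 ± 9.0 against 9.67 ± 1.35 CPM (exact permutation p = 0.143). Of their 2 tested members, Sox9 passed in edgeR adjusted over the list alone, at 3.27 ± 0.76 against 1.43 ± 0.93 CPM. The other, Spp1, made up most of the sum, at 14.2 ± 8.2 against 8.05 ± 2.16 CPM. With no low-count filter, camera called the cholangiocyte markers (adjusted p = 0.0117) and the neutrophil markers (0.0393) as higher; with an estimated correlation both had an adjusted p of 0.626. The summed CPM was 2.36 ± 0.46 against 1.44 ± 0.92 for T and NK cell markers, 2.57 ± 0.86 against 1.47 ± 1.19 for B cell markers and 1.40 ± 1.36 against 0.772 ± 0.496 for neutrophil markers. It was 108 ± 20 against 93.9 ± 21.4 for erythroid and platelet markers, and exact permutation p-values for these 4 lists lay between 0.143 and 0.457. Nearly all of the erythroid and platelet sum was the single gene Alas2, at 107.5 ± 20.1 against 93.3 ± 20.7 CPM. Albumin took 6.45% ± 1.40 of counts with AAV-Trib3 and 6.22% ± 0.94 with AAV-GFP (exact permutation p = 0.8).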

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

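The tests of the acute phase and mitochondrial patterns, and that of isolation stress, were chosen only after the result was seen; the counts over splits and the non-parenchymal covariate were planned. Of 164 sets of 4 libraries examined (named genes, list means and library measures within a group), 10 had 1 library far from the other 3. This share is close to the 5% or so that chance alone gives for independent sets. All 10 lay in AAV-GFP, however, and some sets measure the same transcripts, so the share does not decide whether they arose by chance. The criterion was Dixon's test, the gap to the nearest library as a share of the group's range, at its 95% critical value.

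AAV-GFP replicate 2 stood apart in 8 of these. Mitochondrially encoded transcripts took 32% of its counts, against 14.9% to 16.8% in the other AAV-GFP libraries, and its 10 most abundant genes took 37.4%, against 20.9% to 22.6%. Its mean log2 CPM was 14.3 for mitochondrially encoded transcripts (others 12.5 to 12.7) and 3.29 for p53 targets (others 3.91 to 3.99). Its log2 CPM was 13.3 for mt-Nd4l, 12.4 for Hpx, 10.3 for Cyp2f2 and −1.53 for Cdk1. The mitochondrial share, the mitochondrial list and mt-Nd4l measure largely the same transcripts, and the Cdk1 value rested on very few reads (0.201 CPM). AAV-GFP replicate 3 had a mean of 8.66 for urea cycle and amino acid catabolism genes (others 8.31 to 8.36), and AAV-GFP replicate 4 had a log2 CPM of 9.12 for Oat (others 10 to 10.1).

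Mitochondrially encoded transcripts were lower with AAV-Trib3 when all libraries entered. Without AAV-GFP replicate 2 the list turned to higher with AAV-Trib3, with a camera adjusted p of 0.0367, so the lower level may come from that library alone. What set that library apart was not tested. A biological effect of Trib3 on these transcripts stays open, and the direction in 7 libraries is opposite to that in 8.

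Acute phase genes were high in AAV-Trib3 replicates 1 and 4, where 13 of the 20 list members had their 2 highest values. Macrophage markers were highest in the same libraries within AAV-Trib3 (mean log2 CPM 2.97 and 2.41, against −0.0482 and 1.07 in replicates 2 and 3). Within AAV-GFP, the 2 libraries with most macrophage marker RNA had a lower acute phase mean than the other 2 (difference −0.491 log2 CPM), which argues against RNA of macrophages carried into the preparation as the whole source, although it rests on 4 libraries and the AAV-Trib3 libraries go the other way. AAV-Trib3 replicates 1 and 4 had less Trib3 than AAV-Trib3 replicates 2 and 3 (difference −1.44 log2 CPM). Within AAV-Trib3 the acute phase genes thus did not rise with the Trib3 level. These 4 libraries were divided by their acute phase values, so this order does not decide on an effect of Trib3. Part of the pattern from macrophages, or inflammation or handling that differed between libraries, stays open and was not tested.

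Immediate early genes were lower on average with AAV-Trib3, at a mean log2 CPM of 4.85 ± 0.19 against 5.61 ± 0.75 (SD, exact permutation p = 0.143). AAV-GFP replicate 2, at 4.7, lay below every AAV-Trib3 library (4.73 to 5.13). The median log2 fold change of the 11 immediate early genes was −1.03 with and without the covariate of non-parenchymal markers. The marker mean did not separate the groups, at −0.0543 to 0.808 log2 CPM in AAV-Trib3, within the −0.941 to 1.34 of AAV-GFP. A covariate so alike in both groups could hardly move the difference, so its unchanged value does not decide on RNA of non-parenchymal cells. Different stress during cell isolation cannot be told apart from an effect of Trib3: the 3 heat shock genes differed by 0.159 log2 CPM between the groups, well within their spread between libraries (SD 0.868 and 1.18), and the sign of this difference came from AAV-Trib3 replicate 2 (5.14), since the other AAV-Trib3 libraries (2.62 to 2.9) lay below the AAV-GFP mean of 3.22. The order and duration of the isolations are not given in the sources used here. A lower basal expression with Trib3 may also account for it and was not tested.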

How the results depend on the processing

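The exact permutation of list means, the removal of mitochondrial genes and the estimated correlation in the refits were chosen only after the data had been seen; the other alternatives were planned. Trib3 was higher with AAV-Trib3 in all 19 refits, with an adjusted p from 1.03e-17 to 0.738; it passed the threshold with DESeq2 (log2 fold change 4.204) and without AAV-Trib3 replicate 4 (4.418, adjusted p = 0.0206), and log2 fold changes without 1 library ran from 3.907 to 4.418. The number of genes called stayed at 0 in both directions in edgeR and limma-voom with all libraries, was 3 higher and 3 lower with DESeq2, and ran from 0 to 2 higher and from 0 to 1 lower without 1 library. These were Gm16286 without AAV-GFP replicate 1, Hist2h2aa1, Hnrnpf and Phc3 without AAV-GFP replicate 3, and Trib3 without AAV-Trib3 replicate 4. The real count was 0, which all 35 of the 35 splits of the libraries reach by definition, so that comparison says nothing about chance; the highest other gave 11 genes. For the 9 lists chance is not excluded, since 24 of the 35 splits gave as many lists and the highest other gave 17.

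The number of lists called was 14 with library size alone (adding ATF4 targets, endoplasmic reticulum chaperones, fatty acid synthesis, cholesterol synthesis and PPARA targets) and 0 with an estimated correlation, with fry and with the exact permutation of list means, and ran from 8 to 13 without 1 library. The 0 of the permutation was nearly fixed in advance. Its smallest possible p, 0.0286, passes after adjustment over 32 lists only if most of them reach it. With an estimated correlation in each of the 17 refits that ran camera, 0 lists were called, and the lowest adjusted p was 0.255. An estimated correlation and the permutation count the shared variation of list members between libraries, which the preset value of 0.01 largely leaves out. In the main fit the estimate ran from 0.16 to 0.93 in the 9 lists called. For ATF4 targets it was −0.033, below the preset value, so shared variation does not account for their adjusted p of 0.6 there. Their unadjusted camera p was 0.0454 with the estimate and 0.0183 with the preset value. Of the 9 lists called, 4 kept call and direction in all 8 fits without 1 library: immediate early, periportal, xenobiotic and acute phase genes. Of the 23 lists not called, 14 passed in at least 1 of those fits.

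With the replicate number as a block, 0 genes were called, Trib3 had an adjusted p of 0.684 and 12 lists were called, the 9 and ATF4 targets (adjusted p = 0.0428), endoplasmic reticulum chaperones (0.00309) and cholesterol synthesis (0.0428). The numbers do not pair the libraries: the deviations of same-numbered libraries correlated at −0.27, −0.13, −0.15 and −0.032 (r across genes), and no library correlated best with its own number.

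Of the 70 named genes besides Trib3, 64 kept their direction throughout. Without AAV-GFP replicate 2, log2 fold changes turned for mt-Nd5 (range without 1 library −0.8125 to 0.04055), mt-Nd1 (−0.6832 to 0.04023), mt-Nd4l (−0.6166 to 0.135), Mvk (−1.43 to 0.09323) and Fdft1 (−1.242 to 0.05445). Without AAV-Trib3 replicate 3, Ddit4 turned (−0.1245 to 1.649). The cause was not tested.

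The direction of 19 lists turned in at least 1 fit without 1 library. Their adjusted p over these fits, in either direction, ran from 9.63e-06 to 0.755 for endoplasmic reticulum chaperones, 0.0278 to 0.821 for gluconeogenesis, 1.46e-08 to 0.274 for cholesterol synthesis, 0.00467 to 0.559 for fatty acid oxidation, 0.168 to 0.986 for lipid droplet proteins and 0.0184 to 0.432 for lipoprotein assembly. They ran from 0.161 to 0.967 for insulin signalling, 0.242 to 0.973 for hepatocyte identity, 4.74e-10 to 0.776 for the interferon response, 0.0122 to 0.739 for MHC class I, 0.118 to 0.895 for inflammatory cytokines and 0.00751 to 0.947 for macrophage markers. They ran from 5.47e-05 to 0.459 for endothelial markers, 0.0672 to 0.889 for stellate cell markers, 0.6 to 0.989 for p53 targets, 0.6 to 0.999 for autophagy, 0.000195 to 0.0831 for mitochondrially encoded transcripts, 0.0205 to 0.912 for nuclear respiratory chain subunits and 0.221 to 0.967 for the circadian clock. With the non-parenchymal covariate, lipid droplet proteins (0.603), macrophage markers (0.689) and stellate cell markers (0.786) turned, and autophagy turned with the exact permutation of means (0.855). The cause was not tested.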

Other observations

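The exact permutation of list means and the estimated correlation in fits other than the main one were chosen only after the result was seen, and the other tests given here were planned. The remaining lists did not pass in the main test. Genes of endoplasmic reticulum chaperones were higher with AAV-Trib3 for 16 of 19 members (camera adjusted p = 0.0589), with a list mean of 7.79 ± 0.42 against 7.63 ± 0.42 log2 CPM (SD, n = 4; exact permutation p = 0.6). They passed without AAV-GFP replicate 2 (9.63e-06) or AAV-Trib3 replicate 3 (0.0223) or 4 (4.18e-04) and with library size alone (0.0138), and turned without AAV-Trib3 replicate 2 (0.755). With an estimated correlation their adjusted p was 0.812 with all libraries and lay between 0.721 and 0.83 in those 4 fits. Nuclear-encoded subunits of the respiratory chain were higher for 12 of 16 (adjusted p = 0.12), passed without AAV-GFP replicate 1 (0.0205) or AAV-Trib3 replicate 1 (0.0278) and turned without AAV-GFP replicate 2 (0.912); with an estimated correlation the adjusted p was 0.812 with all libraries and 0.798 and 0.864 in those 2 passing fits. Bile acid synthesis and transport genes were lower for 11 of 16 (adjusted p = 0.13; 0.0111 without AAV-GFP replicate 3), and genes of lipoprotein assembly and cholesterol export were lower for 15 of 18 (adjusted p = 0.159; 0.0184 without AAV-GFP replicate 4, and turned to higher without AAV-GFP replicate 2, 0.234). With an estimated correlation and all libraries these had adjusted p of 0.752 and 0.812, and 0.442 and 0.588 without the library named. Male-biased targets of growth hormone were lower for 7 of 12 (adjusted p = 0.209), and the female-biased genes summed to 24.2 ± 16.6 against 17.2 ± 8.9 CPM (exact permutation p = 0.6).

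Interferon response genes were lower for 12 of 21 members, with a median log2 difference of −0.10 while camera's direction was higher (adjusted p = 0.159; 4.74e-10 without AAV-GFP replicate 4). It was 0.859 with an estimated correlation and all libraries, and 0.255 with one and without AAV-GFP replicate 4. MHC class I genes were lower for 6 of 11, with a median of −0.08 and a mean of 0.06 and camera's direction higher (adjusted p = 0.214; 0.0122 without AAV-GFP replicate 4), and with an estimated correlation 0.812 with all libraries and 0.588 without AAV-GFP replicate 4. Without AAV-GFP replicate 3 both lists turned to lower (0.509 and 0.674). Inflammatory cytokines and NF-kB targets were lower for 7 of 9 (adjusted p = 0.315). Members went both ways for the circadian clock (7 higher, 7 lower, adjusted p = 0.757), lipid droplet proteins and lipases (5 and 9, adjusted p = 0.757), hepatocyte identity (6 and 12, adjusted p = 0.768) and p53 targets (4 and 7, adjusted p = 0.846). For autophagy and lysosome genes, 6 were higher and 9 lower, with camera's direction higher (adjusted p = 0.757). Adjusted over the list alone, Rab7, a GTPase of late endosomes, passed in edgeR at 145 ± 3 against 106 ± 6 CPM (SD, n = 4), and it was also called by DESeq2 over all genes (adjusted p = 0.00463).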
